A study of Arabidopsis thaliana with 2 samples.

How the data were processed

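Total RNA from whole 7-day-old Col-0 seedlings was labelled and hybridized to Affymetrix ATH1 arrays, 1 for untreated seedlings and 1 for seedlings given 200 µM cadmium. The groups were taken from the samples' own treatment labels, since the protocol text of the control sample repeats that of the cadmium sample. The deposited values are log2 expression values made by the authors with RMA from the affy package, per the submitters' processing notes; their versions are not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike and summarises each probe set. The sorted values of both arrays differed by at most 0.11, so a shift of all transcripts in one direction cannot be read from these values. Across 22746 non-control probe sets the arrays had a Pearson r of 0.991, which is across probe sets within this pair of arrays and not across independent replicates. No genome build is named for the values, and no coordinates are given.

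Probe sets were named from a platform table: 13513 had 1 gene symbol, 503 had several and 8730 had none. Probe sets with several symbols or none were not assigned to a gene. Of those with 1 gene, 13436 had an identifier in the gene table of assembly TAIR10.1, which was used for names and for plastid or mitochondrial membership. A gene's value was the mean of its probe sets, giving 13355 genes, of which 147 had more than 1 probe set. A gene was kept if its brighter array was at or above the 40th percentile of non-control values, log2 5.57, which left 7501 genes. The threshold was 2-fold. With 1 array per condition there are no p-values or standard deviations, and the number of arrays limits the precision. Genes are not replicates.

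The named genes were the 14 largest differences in each direction among genes past 2-fold and the floor, with at least 1 probe set not marked as cross-hybridizing and 1 direction over probe sets, and up to 4 members of each gene list by size of difference. The 32 gene lists, the floor, the threshold, this rule and the alternative settings were set before the data were examined. The requirement of at least 3 members for a median, and families of at least 7 genes sharing a symbol stem, were set after the annotation and the overall counts of probe sets had been seen. Lists of peroxidases, root-abundant genes, low-oxygen genes, DUF1005 genes and PIP peptide precursors, and the plastid and mitochondrial groups, were added after gene values had been seen. List members were matched by locus with a check of the symbol, which dropped 6 members. All lists were written from background knowledge.

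Each list median has an order-statistic interval, with its coverage, and a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The interval covers the spread between genes only. With 8 or fewer members, as in every fixed list with a median, it is the full range of the members. The alternatives were no floor, a floor at the 60th percentile, centring on the median of all genes, of reference genes or of spike-ins, removal of a lowess trend (span 0.3), the probe set with the highest mean, leaving out cross-hybridizing probe sets, thresholds of 1.5-fold and 4-fold, and counting probe sets whether named or not. Setting values below the floor to the floor, matching list members by locus alone and leaving AT4G33980 out of the low-oxygen list were added after seeing the data. On simulated arrays with normal noise of SD 0.184, taken from the spread of differences across genes because replicate noise cannot be measured here, 96% of genes planted at log2 1.5 and 100% of those planted at −1.5, 3 or −3 were past 2-fold. These shares check the calculation under that assumed noise and do not give the error of the real arrays. In that simulation 4.5% of 200 unshifted lists lay in the highest or lowest 2.5%. Those lists were drawn at random from the simulated genes, so the share checks only the calculation and not lists of related genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.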

Results

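Transcript levels were measured in whole 7-day-old seedlings of Arabidopsis thaliana, accession Col-0, with and without exposure to cadmium, a toxic metal that binds thiol groups. Each condition was represented by 1 Affymetrix ATH1 array, so 2 arrays in all were compared. Cadmium was given at 200 µM. The exposure time is uncertain: the sample's own labels give 4 h, whereas the protocol and the study design give 6 h. Values are log2 expression summaries for 22746 probe sets besides the array's controls, with a median of 6.19 on the control array and 6.22 on the cadmium array. With 1 array per condition, no difference reported here has a replicate check. No significance test between the conditions was possible, and "higher" and "lower" describe these 2 arrays alone.

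The comparison asks how cadmium alters gene expression in seedlings. Among 7501 named genes past the brightness floor, 38 were at least 2-fold higher in the cadmium array and 57 were at least 2-fold lower, together 1.27% of the genes. The higher group included BGLU28 (AT2G44460), a beta-glucosidase gene known from sulfur starvation, and GSTU25 (AT1G17180), a tau class glutathione transferase gene, both past 4-fold. The lower group was led by AT1G29090 and included EXO (AT4G08950), a gene tied to cell expansion, and EXLA1 (AT3G45970), an expansin-like gene. At 4-fold, 2 genes were higher and 5 were lower. These counts leave out probe sets without a gene name. Among the 6165 of those past the floor, 54 were at least 2-fold higher and 78 lower, a larger share than among named genes. The split between higher and lower depended on scaling. As deposited, 40% of the 95 genes were higher, but centring on 3 reference genes gave 71 higher and 36 lower, 66.4% higher, and centring on the hybridization spike-ins gave 72 higher and 35 lower, 67.3% higher. These centrings subtracted −0.17 and −0.19 log2 units from every difference, which moved the median over genes from −0.03 to 0.15 and 0.16. The larger group turned from lower to higher. Only 3 of 12 listed reference genes could be named. The array's own plant control probe sets for actin, GAPDH and ubiquitin were mostly higher in the cadmium array, unlike the reference genes and spike-ins. Those marked r2 in their names for the 3′ end differed by 0.14, 0.19 and 0.10. Older actin probe sets for the 3′ end and the middle differed by −0.07 and −0.08.

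BGLU28 had a log2 value of 4.97 in the control array and 8.74 in the cadmium array, a difference of 3.77. Its control value lay below the floor, and against the floor of 5.57 the difference was 3.17, so its order relative to GSTU25 is not settled. GSTU25 stood at 7.12 in the control and 10.35 in cadmium, a difference of 3.23. GSTU22 (AT1G78340) followed at 1.95. MSRB5 (AT4G04830), which encodes a methionine sulfoxide reductase, an enzyme that repairs oxidized methionine, was higher by 1.85. LTI30 (AT3G50970), a dehydrin gene induced by cold and drought, was higher by 1.69. AT2G23270 and AT4G37290 were higher by 1.98 and 1.78. The difference was 1.49 for both AT3G28270 and AT3G28220, 1.44 for the peroxidase gene AT4G11290 and 1.39 for both AT1G04770 and AT2G18210. AT5G12340 and AT5G66985 closed the group of 14 at 1.37 and 1.36, the former with a control value below the floor and a difference of 1.19 against it.

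Among the genes lower in cadmium, AT1G29090 went from 8.71 in the control array to 5.72 in the cadmium array, a difference of −2.99. AT3G19680 and AT1G50040 differed by −2.66 and −2.55. EXO stood at 11.67 in the control and 9.25 in cadmium, a difference of −2.42, and EXLA1 also differed by −2.42. AT1G33055 differed by −1.99 and the transcription factor gene BZIP61 (AT3G58120) by −1.96. The next genes were AT2G47440 at −1.80, AT1G26390 at −1.73, AT1G10020 at −1.71 and AT1G02660 at −1.64. The peroxidase genes AT1G30870 and AT4G26010 differed by −1.55 and −1.54, and AT1G62510 by −1.54. Each of these 28 genes kept its 2-fold difference in every alternative in which it had a value. Most alternatives could not have changed that. Each gene has 1 probe set, so the floors and probe-set rules leave its value as it is. The centrings subtracted 0.03, −0.17 or −0.19, too little to take differences of 1.36 or −1.54 under 2-fold. Only the lowess trend and values set to the floor could have done so. Of all 2-fold genes, 5 of the higher and 7 of the lower had a dimmer value below the floor. Against the floor, 36 genes were higher and 53 lower.

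**Figure D1:**
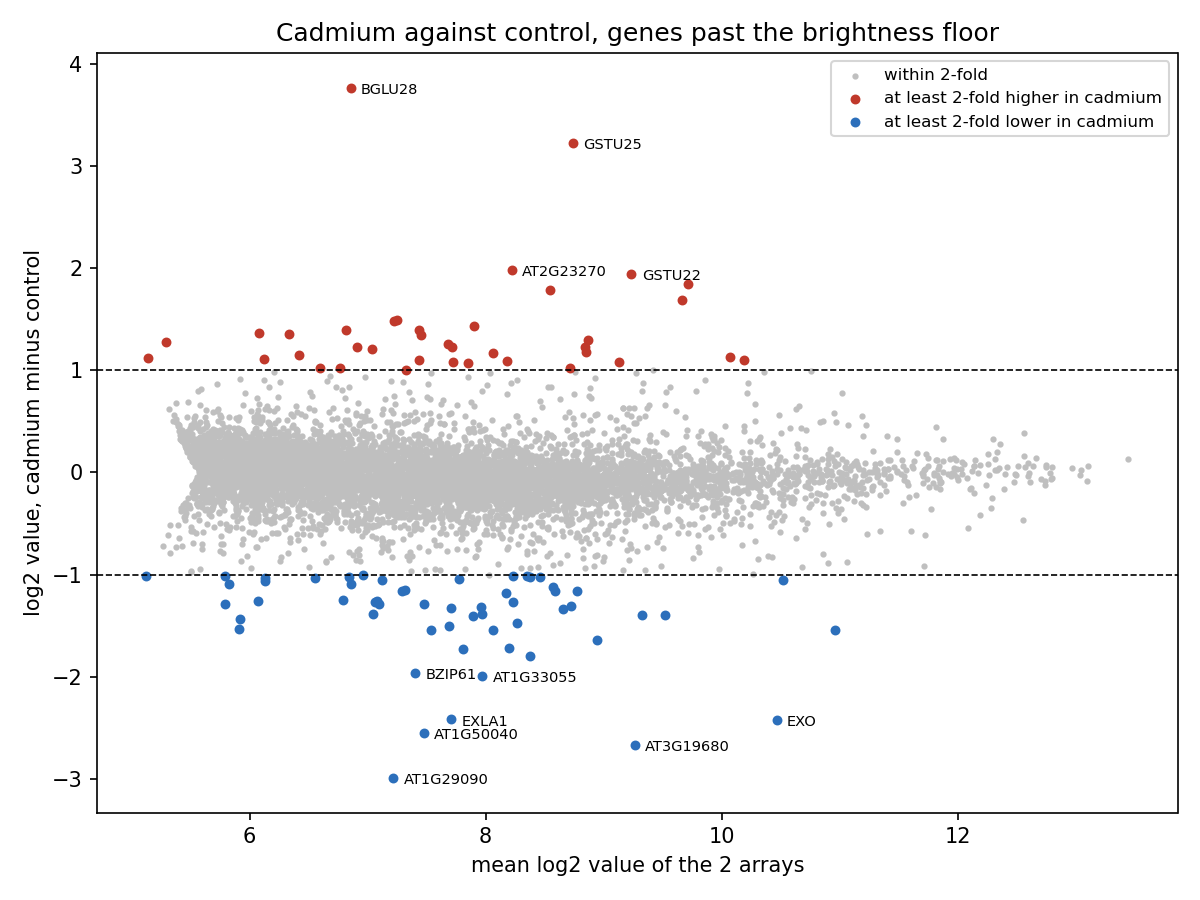
Difference between the cadmium and the control array (log2 units) against the mean log2 value of both arrays, 1 point per gene for 7501 genes past the brightness floor. Dashed lines mark 2-fold. Red points are the 38 genes at least 2-fold higher and blue points the 57 genes at least 2-fold lower in the cadmium array, in the values as deposited; centring on the spike-ins gives 72 and 35.

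The gene lists chosen beforehand numbered 32, with 525 members, of which 80 (15.2%) could be named on the array. Of all non-control probe sets, 13513 of 22746 had 1 gene symbol, a much larger share. Listed genes were thus lost more often than others. A median was given for the 12 lists with at least 3 named members past the floor. In 8 of these the median lay among the highest 2.5% of 10000 random lists matched on mean expression, and in 0 among the lowest 2.5%. Among those 8, the interval of the median, here the range of the members, spanned 0 for the sulfate, tau class, iron, WRKY and abscisic acid lists. The percentile describes these arrays, and a constant shift of all genes does not alter it. Most lists are thin, and those with 3 members have intervals that cover only 75%.

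In the heat shock list, which holds chaperones that bind misfolded proteins, all 5 members past the floor were above 0, with a median of 0.84 (interval 0.78 to 1.17, covering 93.8%) at the 100th percentile, and 2 were at least 2-fold higher. These were AT5G51440 at 1.17 and AT2G29500 at 1.15, both small heat shock protein genes, and Fes1A (AT3G09350) and Hsp70-2 (AT5G02490) stood at 0.84 and 0.80. Without the floor, which brings in dim members, the median was 0.40. The unfolded protein response list, which covers protein folding in the endoplasmic reticulum, had 0 of 5 members past 2-fold and a median of −0.20 (interval −0.63 to 0.21) at percentile 13.7. Within it, CRT1b differed by −0.63 and BZIP60 by 0.21. The 3 proteasome genes had values from 0.05 to 0.10, with a median of 0.06 at percentile 87.2. That median was 0.24 after centring on reference genes.

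Of 8 tau class glutathione transferase genes past the floor, 2 were at least 2-fold higher, GSTU25 and GSTU22, and the other 6 lay within 2-fold. The list's median was 0.30 (interval −0.82 to 3.23), above 99.96% of the random lists, and members went both ways: GSTU27 differed by 0.55 and GSTU26 by −0.82. All 4 members of the xenobiotic response list were above 0, with a median of 0.77 (interval 0.24 to 1.34, covering 87.5%) at the 100th percentile. UGT73B4 and UGT73B5, glycosyltransferase genes, were higher by 1.34 and 1.23, while AT2G04050 and AER differed by 0.31 and 0.24.

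For sulfate uptake and assimilation only 3 of 22 listed genes could be named, so the list says little of the pathway as a whole. Their median was 0.31 (interval −0.21 to 1.02, covering 75%) at percentile 98.6, and 1 of the 3 was at least 2-fold higher. This was APS3 (AT4G14680), which encodes ATP sulfurylase, at 1.02, a value that came just under 2-fold after centring on all genes. SIR, the sulfite reductase gene, differed by 0.31 and APS4 by −0.21. The sulfur starvation list had 6 members past the symbol check, of which only BGLU28 could be named on the array. AT1G04770, higher by 1.39, had also been listed there and was dropped because the symbol recalled for it was not in the gene table. Matched by locus alone, 2 of 2 members past the floor were at least 2-fold higher, while most listed markers had no named probe set. For glutathione and phytochelatin synthesis, 2 of 8 listed genes could be named, the glutathione reductase genes GR1 and GR. They differed by 0.56 and −0.26, both within 2-fold. No gene of the synthesis steps was named, so these values do not describe synthesis.

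In the abscisic acid and dehydration list, 2 of 4 genes were at least 2-fold higher, COR15A at 1.13 and COR15B at 1.07, with COR47 at 0.66 and LEA4-5 at −0.23. Its median was 0.86 (interval −0.23 to 1.13) at the 100th percentile. The control value of COR15A, 4.58, lay below the floor. Against the floor COR15A differed by 0.13, no longer past 2-fold, and the list median was 0.39. The mitochondrial dysfunction markers were all above 0, with a median of 0.33 (interval 0.21 to 1.18) at percentile 99.7. There, 1 of 5 was past 2-fold, NDB2 (AT4G05020), an alternative NADH dehydrogenase gene, at 1.18. Among oxidative stress markers the zinc finger gene STZ (AT1G27730) was higher by 1.10 and the glutaredoxin gene GRX480 differed by 0.89. The WRKY list, transcription factors of defence and stress, was divided. WRKY22 was at least 2-fold lower at −1.28, while WRKY6 and WRKY53 differed by 0.63 and 0.54. The median of these 3 genes, of 19 listed, was 0.54 (interval −1.28 to 0.63, covering 75%) at percentile 99.8.

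The iron deficiency list had a median of 0.23 (interval −0.31 to 0.43) at percentile 99.2, but 0 of its 5 genes were past 2-fold. Its largest values were 0.43 for AT1G47400, −0.31 for BHLH101, 0.28 for AT3G13610 and 0.23 for PYE. Lists for copper deficiency, copper superoxide dismutases and metallothioneins had a single named gene each. AT1G71200 (copper deficiency) differed by 0.42, CCS, the copper chaperone of superoxide dismutase, by −0.20 and the metallothionein gene MT1C by 0.21.

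The 5 photosynthesis genes that could be named, of 35 listed, were all below 0 as deposited and within 2-fold. They include LHCB4.1, LHCB4.2 and LHCB4.3. Their median was −0.12 (interval −0.92 to −0.06) at percentile 20.1. LHCB4.2, a light-harvesting antenna gene, differed by −0.92 and PORB, a chlorophyll synthesis gene, by −0.51. The direction of the list median flipped to 0.050 and 0.061 after centring on reference genes and on spike-ins. That flip rests on a single constant for genes of every brightness. The brightest spike-ins, with mean values of 12.79 and 12.80, differed by only −0.018 and −0.035. LHCB4.1, at 12.80 in the control array, is about as bright and supplies the list median, so the constant may be too large for it. The 3 reference genes had a median of −0.17 at percentile 24.6, which became 0.011 after centring on the spike-ins. Lists of other tissue and rhythm markers held few named genes. The root hair genes EXPA7 and EXPA18 differed by −0.67 and −0.66, the root gene PYK10 by 0.28 and the clock gene GI by −0.22. CCR2 (AT1G80820), a lignin synthesis gene of the phenylpropanoid list, was higher by 1.02.

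**Figure D2:**
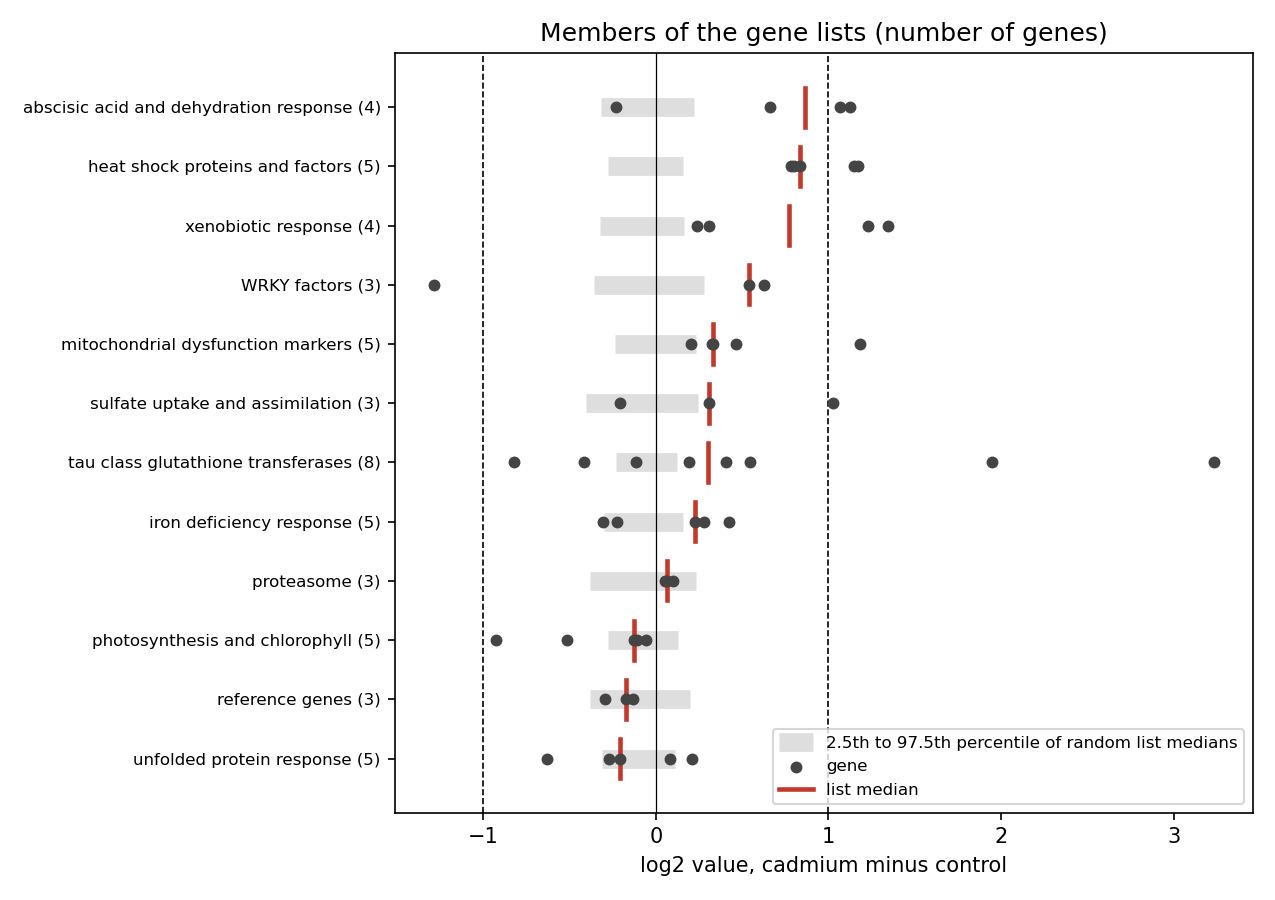
Differences between the cadmium and the control array (log2 units) for members of the 12 gene lists with a median, 1 point per gene, with the number of genes in brackets. Red bars are list medians, grey bands hold the middle 95% of the medians of 10000 random lists matched on mean expression, and dashed lines mark 2-fold. The heat shock median of 0.84 lies right of its band and the photosynthesis median of −0.12 lies within its band, the latter turning to 0.061 after centring on the spike-ins.

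For 2 lists, phi class glutathione transferases and zinc and cadmium transport, the single named member lay below the floor. For 8 lists no member could be named here: iron storage and excess, ethylene, jasmonate, salicylate and defence, camalexin and indole glucosinolates, cell cycle, DNA damage and phosphate starvation. The array's control probe sets also differed. All 18 hybridization spike-in probe sets were lower in the cadmium array, with a median of −0.19 and a range from −0.67 to −0.02. They measure only the transcripts bioB, bioC, bioD and cre, several probe sets to each, so they are not independent of each other. The 25S ribosomal RNA probe set differed by −0.68. In the probe sets marked r2 in their names, the 3′ minus 5′ difference moved by 0.10 for actin, 0.09 for GAPDH and −0.01 for ubiquitin between the arrays. The older actin pair went the opposite way, with −0.07 for the 3′ and 0.25 for the 5′ probe set. The older 3′ and 5′ probe sets differed by 0.20 and 0.06 for GAPDH and by 0.12 and 0.08 for ubiquitin. These controls therefore do not settle whether RNA quality was alike.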

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

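The gene-based comparison leaves out probe sets without a gene name. This part reports values only, with no test. Among 6165 such probe sets past the floor, 54 were at least 2-fold higher and 78 at least 2-fold lower in the cadmium array, and 5 were at least 4-fold higher and 6 at least 4-fold lower. All 11 lie outside the reported comparison. Among the 5 that were at least 4-fold higher, the largest difference was 3.20, from a log2 value of 4.58 in the control array, which is below the floor, to 7.79 in the cadmium array. The next was 3.10, from 7.91 to 11.01. The other 3 differed by 2.40, 2.16 and 2.04. The 6 that were at least 4-fold lower differed by −2.49, −2.35, −2.21, −2.13, −2.10 and −2.05, and 3 of these had a cadmium value below the floor. The genes of all these probe sets are unnamed here.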

How the results depend on the processing

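The floor, the scalings, the probe-set rules and the thresholds were planned; setting values below the floor to the floor, matching list members by locus alone and the low-oxygen list without AT4G33980 were chosen after seeing the data. Of 623 values of 70 named genes under the alternatives, 619 kept their side of 2-fold. Many of these values could not have changed. The floors leave a gene's value as it is, and the probe-set rules can change only genes with several probe sets, 147 of 13355. That count is therefore no measure of robustness. The sign changed in 7 values of 4 genes within 2-fold, LHCB4.3, LHCB4.1, AT4G34270 and PEX4, after centring on reference genes or spike-ins, and in 0 of the 2-fold genes. APS3 went just under 2-fold after centring on all genes, COR15A was at 0.13 against the floor, and Fes1A went past it after centring on reference genes or spike-ins. Of 117 medians of the 12 fixed lists and the plastid-encoded genes, 103 stayed within the list's interval and 14 left it, and 0 of those at an extreme percentile reversed. For the fixed lists that interval is the full range of the members, so staying within it is a weak check. The added low-oxygen list is not among these medians. Its median of −0.16 became 0.016 after centring on reference genes, a constant shift that does not alter its place among other genes. The proteasome median by locus alone was 0.074.

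The counts of higher and lower genes, 38 and 57, became 71 and 36 after centring on reference genes and 72 and 35 after centring on spike-ins. They became 150 and 250 at 1.5-fold, 2 and 5 at 4-fold, and 95 and 141 when probe sets were counted. Those shifts follow from the settings themselves. The heat shock median was 0.40 with no floor. After centring on reference genes, medians were 0.24 (proteasome), 0.72 (WRKY), 0.050 (photosynthesis), 0 (reference genes) and 0.28 (plastid-encoded). After centring on spike-ins they were 0.25, 0.73, 0.061, 0.011 and 0.29. The proteasome median was 0.034 after centring on all genes and 0.14 after lowess, where the reference gene median was −0.094. Dim genes lie near background, which limits what their differences show.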

Other observations

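The tests on root-abundant genes, low-oxygen genes, nuclear photosynthesis genes and genes of like brightness were chosen after some or all of the values they use had been seen. The test on mitochondrial genes was written before their values were seen, but after the plastid pattern was. In total, 32 fixed lists, 22 symbol families, 5 added lists and 8 organelle groups were looked at, so some extremes arise with no effect at all.

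Among the 22 symbol families, 4 had medians in the highest 2.5% of random lists and 1 in the lowest 2.5%. UDP-glycosyltransferase genes (UGT) had a median of 0.10 over 36 genes at percentile 99.8, with 22 above 0 and 2 past 2-fold. Tetraspanin genes (TET) had a median of −0.27 over 7 genes at percentile 1.83, with TET10 at −0.80 and TET3 at −0.65 and 0 past 2-fold. Both medians kept their direction under every scaling. The tau class family repeats a fixed list, and the RPL and RPS families consist of plastid genes, with medians of 0.70 and 0.14.

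Some genes were singled out after their values were seen. Genes of the DUF1005 family, of unknown function, were AT3G19680 at −2.66, AT1G50040 at −2.55 and AT1G10020 at −1.71. Precursors of secreted PIP peptides were AT2G23270 at 1.98, AT4G37290 at 1.78 and AT4G28460 at 1.10. Because these lists consist of genes noticed for their values, their percentiles carry no weight and only values are given. THE1 (AT5G54380), a receptor kinase gene of cell wall sensing, was at −1.51, and the expansin-like gene EXLA2 at −1.09, or −0.80 against the floor, since its cadmium value lay below it.

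Plastid-encoded genes lay slightly to the higher side in the cadmium array: 53 of 67 were above 0, with a median of 0.10 (interval 0.06 to 0.18) at the 100th percentile, and medians of 0.21 for ribosomal protein genes, 0.42 for 3 RNA polymerase genes and 0.06 for photosystem genes. An offset of the whole array is argued against, since 82.1% (exact interval 70.8% to 90.4%) lay above the median of genes of like brightness, although genes of one operon are not independent and the interval is too narrow for that reason. More shoot tissue is not decided. The nuclear photosynthesis median of −0.12 (interval −0.92 to −0.06) met the outcome set against it. Yet that list holds 5 of 35 members, and its median lies within the spread of matched random lists, −0.28 to 0.13. This spread is wide beside the plastid median, and cadmium itself may have lowered those 5 genes. After centring on spike-ins the list median was 0.061 beside a plastid median of 0.29, but the brightest spike-ins differed by only −0.018 and −0.035. More organelle RNA of every kind stays open, because the mitochondrial median was 0.17 (interval −0.05 to 0.46, 8 genes). An effect of cadmium on plastid transcripts also stays open and was not tested, with 1 array per condition.

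Of 35 class III peroxidase genes past the floor, 4 were at least 2-fold lower, AT1G30870, AT4G26010, AT3G49960 at −1.54 and AT3G28200 at −1.16, and 1 was higher; the median of −0.12, at percentile 3.45, flipped to 0.057 after centring on reference genes, when 3 rather than 4 were 2-fold lower. AT3G49960 had a cadmium value below the floor and differed by −1.10 against it. The peroxidase list was added after gene values had been seen, so its percentile is no test. Less root tissue as a part of the pattern cannot be told apart from other causes, since 15 root-abundant genes had a median of 0.017 with an interval of −0.66 to 0.28 that spans the bound of −0.5 set for the test. As the whole cause of the 4 lower peroxidases, less root tissue is argued against only under an untested assumption. The 15 genes must be as confined to root as the peroxidases and not altered by cadmium itself. Less root would then lower both sets alike, yet 8 of the 15 were above 0 and the lowest was −0.88. The interval's lower bound of −0.66 also lies above the −1.16 of AT3G28200. This comparison was added after the undecided outcome, and the 4 genes, picked for being past 2-fold, may have overstated differences. Fewer root hair cells stay open, as the root-abundant list includes EXPA7 and EXPA18, and so does an effect of cadmium.

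Of 19 genes on a low-oxygen list, 5 were at least 2-fold lower, among them AT1G33055 at −1.99 and AT5G42200 at −1.41, and 1, AT5G66985, was higher. In all 7 were above 0, among them CML38 at 0.58, PDC2 at 0.28 and AT4G17260 at 0.23, opposite to what lower oxygen in the control would give. After centring on reference genes or spike-ins 3 were lower, and AT4G10270, at −1.01, differed by −0.060 against the floor. The median of −0.16 (interval −1.01 to 0.23) lay at percentile 1.84, and centring on reference genes, a constant shift that leaves the percentile as it is, brought the median to 0.016. The percentile depends on AT4G33980, whose membership is uncertain and which was included after its value was seen: without it the median was −0.12 at percentile 5.54, no longer below the 2.5th. The whole low-oxygen list was added after gene values had been seen, so neither percentile is a test. Lower oxygen around the control seedlings may account for some of the lower genes and stays open, as does an effect of cadmium. The 13 members under 2-fold lay at percentile 55.1, which decides nothing, because leaving out the members past 2-fold by itself draws the rest toward the middle.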
